A study of Mus musculus with 24 samples.

How the data were processed

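RNA of 24 left kidney samples of wildtype mice was sequenced by the submitters, 4 libraries in each of 6 groups. The libraries were made with a stranded RNA kit from Trizol extracts, per the labels' protocols. The deposited FPKM values, fragments scaled for transcript length and library depth, come per gene and per transcript, 1 column per library, per the file headers. The submitters' processing notes name cutadapt, HISAT2 and StringTie and the mouse build GRCm38, and the versions are not given in the sources used here. From the values, every gene of the gene table has a mean of at least 0.5002 FPKM in some group, so the deposited table had been filtered, and all its genes are typed protein coding. A line emptied before the tables were provided is not used here. Of 14407 genes, 14385 have an ID in the reference annotation and 13209 the same locus, and coordinates are printed as the table gives them. Groups come from the labels, and the replicate numbers of the vehicle libraries come from the names of the tables' columns. No per-sample column was left out.

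Read counts are not used here. The relative depth of each library was estimated from the transcript table, whose smallest steps give the value of 1 fragment, so it is an estimate, and no counting interval was computed. The transcript table was also searched for genes with a switching transcript, meaning at or under 0.05 FPKM in 3 or more libraries of 1 group and at or over 0.5 FPKM in 3 or more libraries of another group of the same surgery. Genes with an FPKM of at least 1 in at least 4 of the 24 libraries, 13127 in all, were tested on the log2(FPKM + 1) scale. Levels at 0 are given as listed, since a 0 can also be a failed estimate.

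Comparisons were made with limma 3.58.1 in R 4.3.3 by a linear model with 1 mean per group, 18 residual degrees of freedom and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the tested genes of each comparison and a threshold of 0.05. "Rose" and "fell" are said of genes past that threshold. There were 10 comparisons: UUO against sham under each of 3 treatments, each course against vehicle in each surgery, the courses against each other in UUO, and 2 interactions of course and surgery. Sets were tested with the function camera of limma at a preset inter-gene correlation of 0.01, over 44 lists of genes, of which 42 had at least 3 tested genes. The lists, the comparisons, the filter, the threshold, the alternatives and the rule for naming genes were chosen before the data were examined. Counts of members past the threshold are given over all genes and adjusted over the list alone.

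Genes were named by this rule. In each comparison the 8 largest increases and the 8 largest decreases among called genes were named if the mean was at least 5 FPKM in the higher group and the libraries of the groups did not overlap, predicted genes aside. If fewer than 3 passed, the 5 genes with the smallest p were named as not past the threshold. Where 20 or fewer genes passed, all were named. Up to 4 members with the smallest p were named for each list described. A fixed set of 16 genes of injury, fibrosis, tubule function and adenosine signalling was named in UUO vehicle against sham vehicle and in both comparisons of a course with vehicle in UUO. Results of some genes that this rule names are not reported here.

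The reversal of the obstruction change was measured as the correlation, across genes, of a course's change in UUO with the obstruction change under the other course, which shares no library with it. The agreement of the courses was set against 100 simulated pairs of unchanged groups that share their controls. Other splits of the libraries into groups of the same sizes were fitted in full where there were 35, and 100 of them were drawn for the interactions.

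The fit was tested on simulated data for 13127 genes with 200 of them changed, in 10 draws per comparison. It recovered between 36 and 46.4% of changes of log2 0.5 and between 79 and 83.5% of changes of log2 1. False calls made up 0.6 to 3.7% of calls in the comparisons with sham libraries. With residuals shuffled gene by gene they made up 28.7, 27.1 and 29% in UUO early against UUO vehicle, UUO late against UUO vehicle and UUO early against UUO late. With residuals shuffled by whole libraries, the form run before the other, they made up 15, 14 and 39.5%. As counts, false calls averaged 50.7, 46.1 and 51.5 per draw under gene shuffling and 28.8, 28.9 and 187.2 under library shuffling. The draws hold 200 changed genes, so neither the shares nor the counts carry over directly to comparisons with few calls. With no list changed and 30 draws, the preset correlation called on average 12.1, 12.9 and 12.8 of 42 lists in those comparisons under library shuffling, and 4.5 and 4.6 in sham early and sham late against sham vehicle. Under gene shuffling it called at most 0.2 on average. The estimated correlation called at most 0.07 on average in either form.

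The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, rescaling to the same sum in every library, a fit of the compared groups alone, robust estimation with quality weights, the replicate number as a block, an estimated correlation for the lists, and leaving out each library in turn. Leaving out genes with a switching transcript, and leaving out replicate 4 of both UUO early and UUO late, were added after the data were seen. The labels do not say that replicate numbers pair the libraries across groups, so the block was used as an alternative alone. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.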

Results

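RNA sequencing measured gene expression in whole left kidneys of wildtype mice after a sham operation or unilateral ureteral obstruction (UUO). In UUO the ureter of 1 kidney is closed so that urine cannot drain, a widely used model of tubular injury and kidney fibrosis. The mice received vehicle or istradefylline, an antagonist of the adenosine receptor encoded by Adora2a, in a course labelled as early or as late intervention. The 6 groups (sham vehicle, sham early, sham late, UUO vehicle, UUO early and UUO late) held 4 libraries each, 24 in all. The labels give neither the dose, the days of either course nor the hour of collection, and they do not say that the 4 libraries of a group came from separate mice. The p-values therefore measure the spread between these libraries.

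The estimated depth averaged 10435000 fragments in sham vehicle, 10220000 in sham early and 8137500 in sham late libraries. It averaged 9617500 in UUO vehicle, 12582500 in UUO early and 11400000 in UUO late libraries, and single libraries ranged from 7720000 to 19680000 fragments. The 10 most abundant genes took 21.8% of the summed FPKM in sham vehicle kidneys and 12.9% in UUO vehicle kidneys. The deposited gene table listed 14407 protein-coding genes, of which 13127 passed the filter on low values. The first principal component held 77.7% of the variance of these genes and the next 3.6%. No pair of libraries had identical values, and the highest correlation between any pair was r = 0.988 across genes, which are not independent replicates.

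The comparison of UUO vehicle with sham vehicle kidneys addressed the effect of obstruction without drug. Obstructed kidneys had far more RNA of tubular injury genes. Havcr1, which encodes kidney injury molecule 1 (ENSMUSG00000040405, GRCm38 chromosome 11, 46735080 to 46779578), rose from 0.733 ± 0.522 to 303 ± 76.2 FPKM (mean ± SD, n = 4 here and below), a log2 change of 7.46 (SE 0.28, adjusted p = 3.2e-14). Lcn2, a secreted iron-siderophore binding protein used as an injury marker, rose from 3.09 ± 2.75 to 166 ± 69.8 FPKM (log2 5.46, adjusted p = 1.42e-09). All 21 measured members of the tubular injury list rose, with a median log2 change of 3.05, among them the adhesion molecule Vcam1 (0.612 to 48.1 FPKM), the secreted phosphoprotein osteopontin Spp1 (338 to 4857 FPKM) and the transcription factor Sox9 (0.138 to 15.5 FPKM). The list was called by camera at adjusted p = 3.17e-10, and at adjusted p = 0.0852 with an estimated correlation. The protease inhibitor Timp1 rose from 0.614 to 126 FPKM (log2 6.28), and Ubd, a ubiquitin-like modifier, from 1.22 to 82.4 FPKM (log2 5.24). Sprr2f, a small proline-rich protein of stratified epithelia from a family of similar genes and so uncertain, and the matrix protease Mmp7 were listed at 0 in each sham vehicle library. In the UUO vehicle libraries 1 to 4, Sprr2f was at 84.9, 78.2, 65.0 and 43.9 FPKM and Mmp7 at 25.2, 64.1, 24.8 and 60.6 FPKM.

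**Figure D1:**
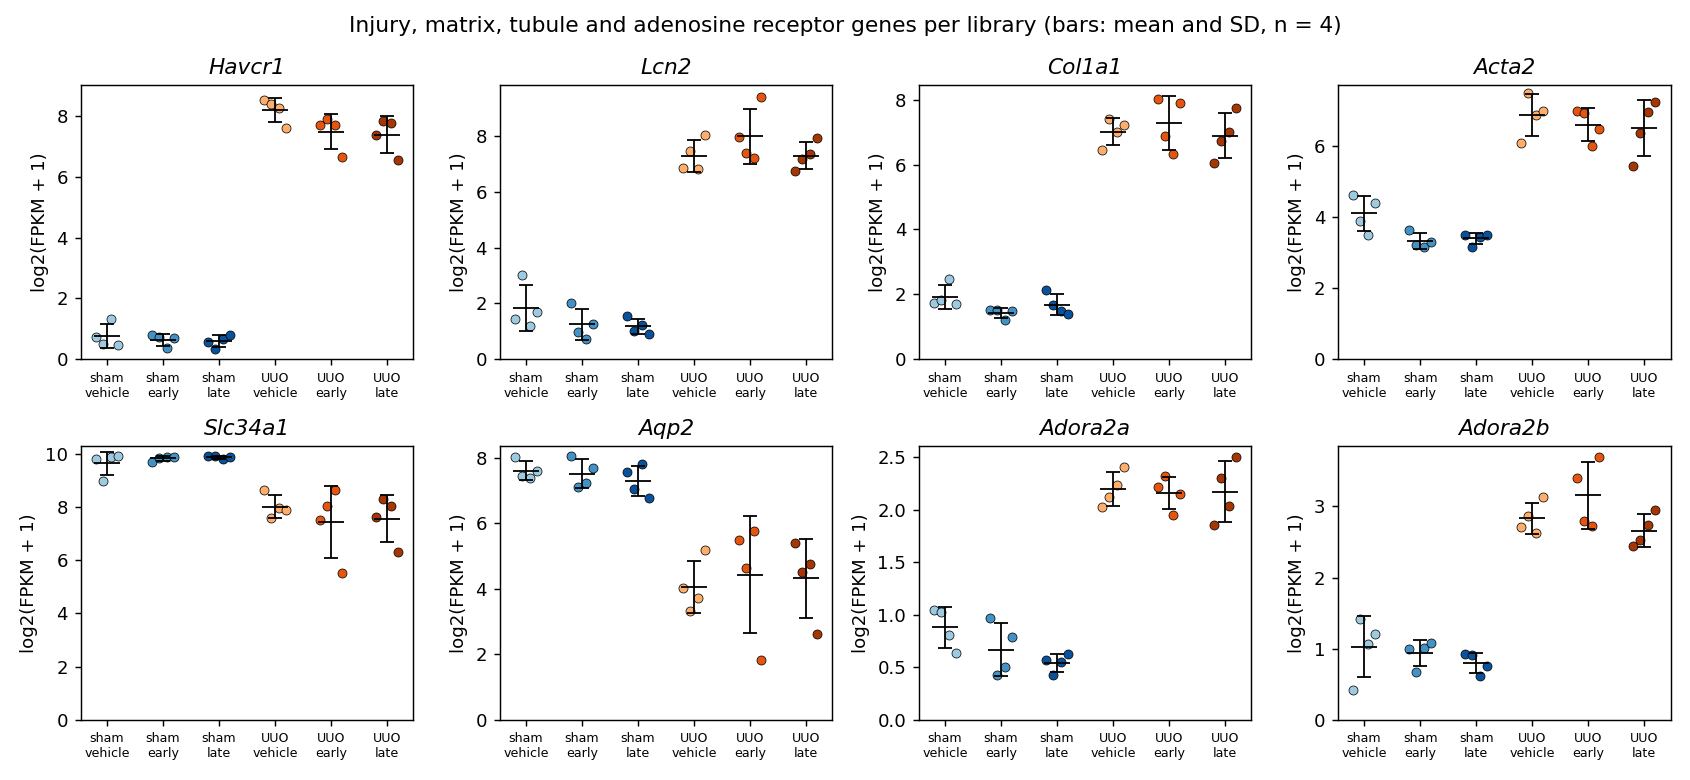
Expression of Havcr1, Lcn2, Col1a1, Acta2, Slc34a1, Aqp2, Adora2a and Adora2b as log2(FPKM + 1) in each library of the 6 groups (points), with group mean and SD (bars, n = 4). Havcr1 averaged 303 FPKM in UUO vehicle against 0.733 FPKM in sham vehicle kidneys, and the 3 obstructed groups overlap for each of the 8 genes.

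Extracellular matrix and mesenchymal genes were higher after obstruction. The fibrillar collagen genes Col1a1 and Col3a1 rose from 2.91 ± 1.12 to 133 ± 34.9 FPKM (log2 5.09, SE 0.34, adjusted p = 1.09e-10) and from 2.79 ± 0.481 to 95.4 ± 26 FPKM (log2 4.63, SE 0.27, adjusted p = 1.38e-11). Each of the 31 measured matrix genes rose, with a median log2 change of 2.67, including Sparc, a collagen-binding glycoprotein (31.4 to 317 FPKM), and the basement membrane collagen Col15a1 (2.14 to 29.3 FPKM). This list was called at adjusted p = 4.49e-09, and at adjusted p = 0.255 with an estimated correlation. Fn1, which encodes fibronectin, rose by a log2 change of 3.37, and Acta2, the smooth muscle actin of myofibroblasts, from 17.0 to 124 ± 47.0 FPKM (log2 2.77, adjusted p = 4.44e-07). All 16 myofibroblast and pericyte genes rose, such as the surface glycoprotein Thy1 (0.548 to 33.3 FPKM), the intermediate filament gene Vim (8.07 to 59.8 FPKM) and the matrix protein gene Ltbp2 (0.0175 to 7.97 FPKM). Their list had adjusted p = 0.000427, and adjusted p = 0.255 with an estimated correlation. Tgfb1, the central fibrogenic growth factor, rose by a log2 change of 2.37. In the TGF-beta list 14 of 19 members rose and 1 fell, or 16 and 1 when adjusted over the list alone (adjusted p = 0.00611, and adjusted p = 0.228 with an estimated correlation). Among matrix proteases and inhibitors 18 of 19 rose and 1 fell, with the protease Adamts1 from 5.23 to 40.2 FPKM (adjusted p = 1.52e-05, and adjusted p = 0.228 with an estimated correlation).

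Genes of immune cells and inflammatory signalling were also higher. Of 24 macrophage genes 23 rose and 1 fell, with a median log2 change of 3.27, such as the complement component C1qa (14.4 to 327 FPKM) and the surface receptor Adgre1 (0.568 to 16.9 FPKM). The list had adjusted p = 8.51e-09, and adjusted p = 0.228 with an estimated correlation. Lyz2, a lysozyme of myeloid cells whose level is uncertain where reads could be shared with its copy Lyz1, rose from 15.2 to 759 ± 309 FPKM. The chemokine Ccl8 rose from 0.383 to 67.4 FPKM. Of 28 cytokine and chemokine genes 27 rose, including the monocyte attractant Ccl2 (0.374 to 47.8 FPKM), the neutrophil attractant Cxcl1 (0.860 to 33.3 FPKM) and the cytokine Lif (0.103 to 5.05 FPKM). The list had adjusted p = 8.48e-08, and adjusted p = 0.211 with an estimated correlation. All 18 NF-kB and inflammasome genes rose, among them Icam1, an adhesion molecule, and the NF-kB subunit Relb, with adjusted p = 2.33e-08 for the list and adjusted p = 0.228 with an estimated correlation. All 15 antigen presentation genes rose, such as the class II gene H2-Aa (41.5 to 475 FPKM), at adjusted p = 2.91e-07 and adjusted p = 0.228 with an estimated correlation. Interferon response genes (20 of 22 rose, adjusted p = 1.91e-05), complement genes (15 of 17, adjusted p = 2.41e-05), dendritic cell genes (8 of 8, adjusted p = 0.0312) and T cell genes (11 of 11, adjusted p = 0.037) were called as well. They lost the call at adjusted p = 0.229, adjusted p = 0.211, adjusted p = 0.255 and adjusted p = 0.565 with an estimated correlation. The T cell call also ended without 1 of the 8 libraries. The neutrophil list was not called (adjusted p = 0.562), though 4 of its 6 measured genes rose, with S100a9, a calcium-binding protein of neutrophils, at 2.61 ± 3.23 FPKM in sham and 31.6 ± 23.2 FPKM in UUO vehicle kidneys.

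Genes of cell division and stress were higher. All 23 cell cycle genes rose, such as the topoisomerase Top2a (0.555 to 4.43 FPKM) and the cyclin Ccna2 (1.13 to 6.45 FPKM), at adjusted p = 5.58e-06 and adjusted p = 0.255 with an estimated correlation. Of 18 p53, senescence and apoptosis genes 16 rose and 1 fell, with the cyclin-dependent kinase inhibitor Cdkn1a from 3.09 to 32.2 FPKM (adjusted p = 0.0152, and adjusted p = 0.228 with an estimated correlation). Of 16 immediate early genes 15 rose, with the stress-induced transcription factor Atf3 from 1.17 to 13.1 FPKM (adjusted p = 0.000805, and adjusted p = 0.291 with an estimated correlation).

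Tubule transport and energy metabolism genes were lower after obstruction. Of 30 proximal tubule genes 29 fell, with a median log2 change of -1.82, at adjusted p = 1.99e-13 and adjusted p = 0.228 with an estimated correlation. The sodium-phosphate cotransporter gene Slc34a1 fell from 820 to 267 FPKM (log2 -1.63, SE 0.47, adjusted p = 0.00482), the endocytic receptor gene Lrp2 from 74.4 to 20.9 FPKM and the amino acid transporter gene Slc6a19 from 46.2 to 7.63 FPKM. Aqp2, the vasopressin-regulated water channel of the collecting duct, fell from 198 ± 41.3 to 17.9 ± 11.8 FPKM (log2 -3.56, SE 0.65, adjusted p = 7.31e-05). Umod, the uromodulin gene of the loop of Henle, fell from 637 to 349 FPKM (log2 -0.86, adjusted p = 0.00672). Egf, the epidermal growth factor gene, fell from 64.6 to 2.57 FPKM, and the calcium-binding protein genes Pvalb and Calb1 from 37.9 to 0.127 and from 59.4 to 6.42 FPKM. The cytochrome P450 genes Cyp2d9 and Cyp2d12 fell by 3.79 and 3.51 on the log2 scale. The last 2 belong to a family of similar sequences, so their levels are uncertain where reads could be split among members. Nccrp1 (45.5 to 1.21 FPKM) and the selenium-independent glutathione peroxidase gene Gpx6 (39.3 to 2.26 FPKM) were the remaining members of the 8 with the largest decreases. Loop of Henle (7 of 9 fell, adjusted p = 4.22e-05), intercalated cell (7 of 10, with the anion exchanger Slc26a4 from 23.8 to 5.75 FPKM, adjusted p = 5.61e-05), principal cell (8 of 10, adjusted p = 0.000731) and distal convoluted tubule genes (5 of 8, with the kallikrein Klk1 from 1636 to 246 FPKM, adjusted p = 0.000895) were called lower. Their adjusted p = 0.228, adjusted p = 0.228, adjusted p = 0.208 and adjusted p = 0.208 with an estimated correlation.

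Of 24 oxidative phosphorylation genes 23 fell, with a median log2 change of -0.82, such as the succinate dehydrogenase subunit Sdhb (226 to 77.1 FPKM), at adjusted p = 1.14e-15 and adjusted p = 0.208 with an estimated correlation. Of 26 fatty acid oxidation genes 23 fell and 1 rose, such as the medium-chain acyl-CoA dehydrogenase Acadm (243 to 68.8 FPKM), at adjusted p = 3.13e-12 and adjusted p = 0.228 with an estimated correlation. The antioxidant and NRF2 list was called lower (adjusted p = 0.00328, and adjusted p = 0.255 with an estimated correlation) with 8 of 19 members falling and 3 rising. In it the superoxide dismutase genes Sod1 and Sod2 fell, while Nfe2l2, which encodes the transcription factor NRF2, and its target Hmox1, a heme oxygenase, rose (15.8 to 37.2 FPKM for Hmox1). The glycolysis and hypoxia list was called lower at adjusted p = 0.01 (adjusted p = 0.255 with an estimated correlation) with 7 members falling and 6 rising, a median log2 change of -0.076 and a mean of 0.021. The hexokinase Hk2 rose from 0.187 to 5.62 FPKM and the carbonic anhydrase Car9 fell from 7.69 to 1.47 FPKM. Of 19 circadian clock genes 8 fell and 5 rose, or 9 and 5 when adjusted over the list alone, with the clock output genes Dbp (67.8 to 25.4 FPKM) and Hlf (14.8 to 3.41 FPKM) lower. That list was called lower at adjusted p = 0.0151, and at adjusted p = 0.228 with an estimated correlation.

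Istradefylline's target Adora2a rose from 0.852 ± 0.242 to 3.61 ± 0.536 FPKM (log2 1.32, SE 0.14, adjusted p = 9.06e-08) and the related receptor gene Adora2b from 1.10 ± 0.562 to 6.18 ± 1.14 FPKM (log2 1.80, SE 0.21, adjusted p = 2.2e-07). Adora1, another adenosine receptor gene, was at 1.66 FPKM in sham and 2.01 FPKM in UUO vehicle kidneys and did not pass (adjusted p = 0.549), and Adora3 is not analysed here. Nt5e, whose product makes extracellular adenosine, was at 9.29 and 12.4 FPKM (log2 0.39, SE 0.19, adjusted p = 0.0773). It passed when FPKM were rescaled to the same sum in every library (adjusted p = 0.025) and without replicate 4 of sham vehicle (0.0323) or of UUO vehicle (0.0166). Ahcy and Adk, which clear S-adenosylhomocysteine and adenosine, fell from 176 to 38.0 and from 20.6 to 8.10 FPKM. The list of 23 adenosine genes was not called (9 rose, 6 fell, median log2 0.204 with a test direction of lower, adjusted p = 0.242), nor was the list of cAMP-responsive genes (10 of 15 rose, 1 fell, adjusted p = 0.278).

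By limma with Benjamini-Hochberg adjustment 8790 of the 13127 genes passed, 6604 higher and 2186 lower in obstructed kidneys, and camera called 26 of 42 lists, 16 higher and 10 lower. With an estimated correlation camera called 0 lists (8 at unadjusted p). In 37 of the 42 lists the counts of members that rose or fell were the same when adjusted over the list alone. FPKM scaling placed the median log2 change of all tested genes at 0.32 rather than 0, and median-of-ratios scaling moved it to 0.02 and changed the split to 4199 higher and 3899 lower. Changes of lists and genes above are therefore to be read against 0.32. The podocyte list (5 rose, 1 fell, median 0.209, adjusted p = 0.805) and the endothelial list (7 rose, 1 fell, or 6 and 1 when adjusted over the list alone, median 0.355, adjusted p = 0.957) had medians near that shift and a test direction of lower.

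**Figure D2:**
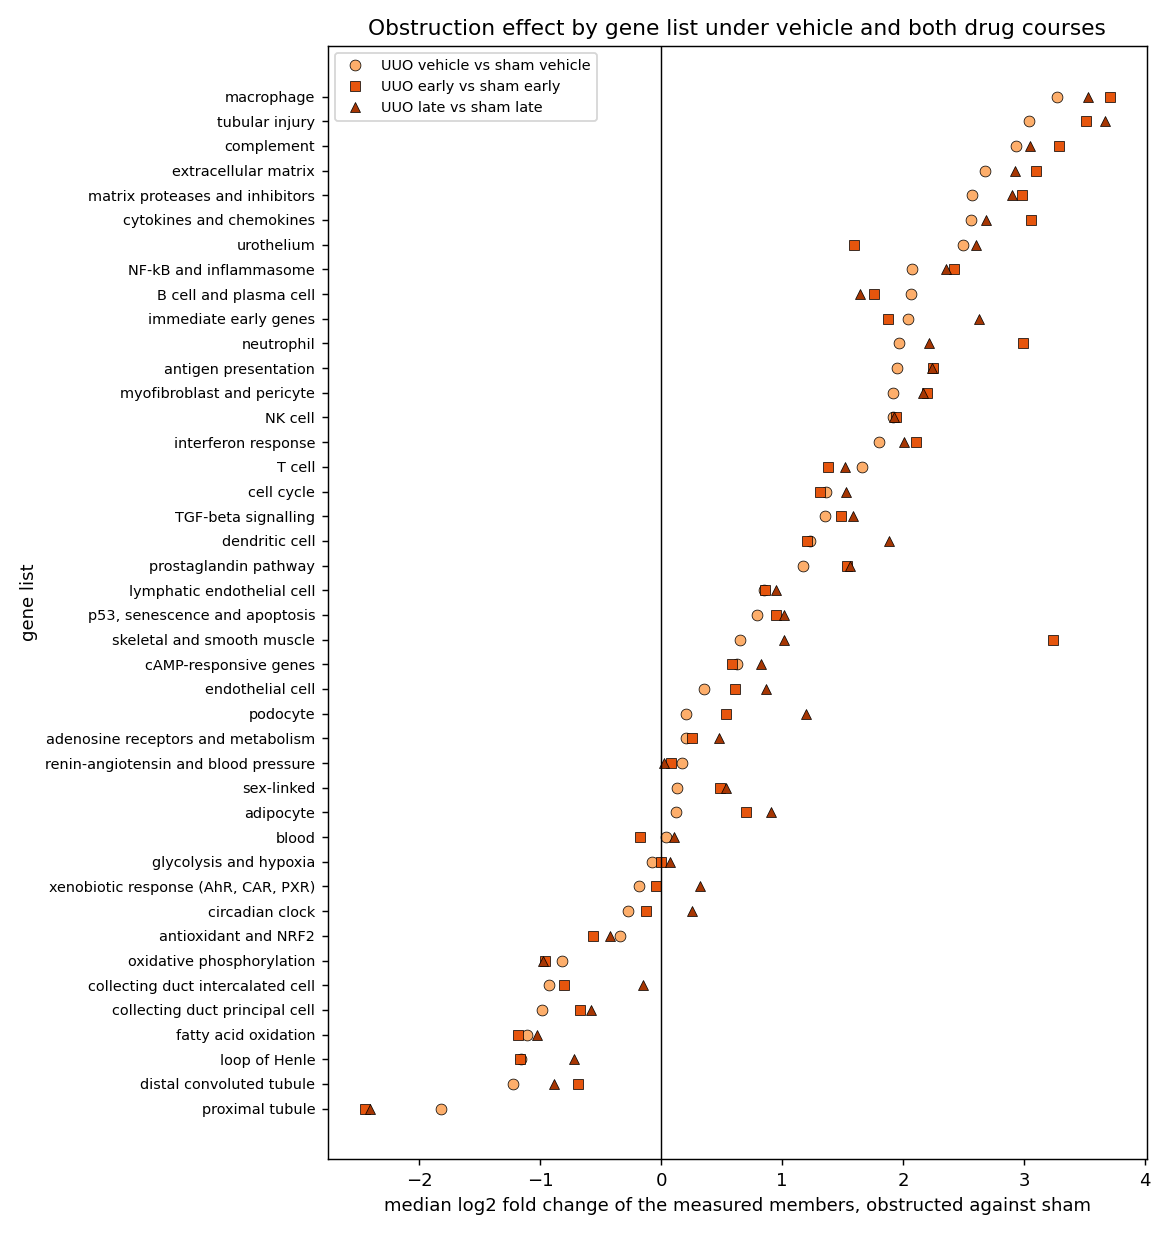
Median log2 change of the members of each gene list in UUO against sham kidneys under vehicle, the early course and the late course (points, on the log2(FPKM + 1) scale). The proximal tubule list had a median of -1.82 and the matrix list a median of 2.67 in UUO vehicle against sham vehicle kidneys.

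The comparison of UUO early with sham early kidneys asked what obstruction changed under the early course. The largest increases were those of Havcr1 (0.564 to 188 ± 61.1 FPKM, log2 6.85), the lysozyme gene Lyz2 (8.46 to 1138 ± 750 FPKM, log2 6.75), Lcn2 (1.52 to 309 ± 247 FPKM), Timp1 and the complement gene C3 (2.11 to 233 FPKM, log2 6.29). Ccl8, Mmp7 and Sprr2f followed. Mmp7 and Sprr2f were each listed at 0 in 3 of the 4 sham early libraries. The largest decreases were those of Egf (98.2 to 5.27 FPKM), the thyroxine carrier Ttr (257 to 26.3 FPKM), the nuclease Dnase1 (274 to 27.2 FPKM), the anion transporter Slc22a7 (log2 -3.69), Cyp2d9, Cyp2d12, Nccrp1 and Gpx6. All 31 matrix genes (median log2 3.10), all 21 tubular injury genes (3.51) and 23 of 24 macrophage genes (3.71) rose, while all 30 proximal tubule genes (-2.45) and all 24 oxidative phosphorylation genes (-0.961) fell. These lists had adjusted p = 8.33e-09, 6.07e-09, 6.74e-09, 9.39e-17 and 9.39e-17, and with an estimated correlation adjusted p = 0.317, adjusted p = 0.146, adjusted p = 0.263, adjusted p = 0.254 and adjusted p = 0.254. Over all genes 9441 passed, 7176 higher and 2265 lower, and 23 lists were called, 14 higher and 9 lower. Median-of-ratios scaling moved the median of all genes from 0.40 to 0.04 and the split to 4601 higher and 4220 lower.

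The comparison of UUO late with sham late kidneys asked the same of the late course. Havcr1 rose from 0.514 to 178 ± 63.1 FPKM (log2 6.81), Lyz2 from 9.56 to 834 ± 283 FPKM, Lcn2 from 1.28 to 163 ± 57.5 FPKM. Timp1, C3, Sprr2f, Mmp7 and Retnla, a secreted product of alternatively activated macrophages (0.0477 to 57.7 FPKM), were the others of the 8 largest increases. The largest decreases were those of Slc22a7 (202 to 9.22 FPKM, log2 -4.85), Pvalb, Egf, the amino acid transporter Slc7a13 (330 to 19.3 FPKM), Gpx6, the brush border protease Mep1b, Nccrp1 and the steroid-reducing enzyme Akr1c18. Matrix genes (31 of 31, median log2 2.93), tubular injury genes (21 of 21, 3.67) and macrophage genes (23 of 24, 3.53) rose, and proximal tubule genes (30 of 30, -2.41) and oxidative phosphorylation genes (24 of 24, -0.976) fell. The lists had adjusted p = 1.75e-06, 1.15e-07, 3.81e-07, 5.73e-18 and 4.24e-18, and with an estimated correlation adjusted p = 0.382, adjusted p = 0.217, adjusted p = 0.3, adjusted p = 0.3 and adjusted p = 0.217. Over all genes 9920 passed, 7750 higher and 2170 lower, and 24 lists were called, 15 higher and 9 lower. Median-of-ratios scaling moved the median of all genes from 0.49 to 0.04 and the split to 4727 higher and 4323 lower. In these 2 comparisons the counts adjusted over the list alone were the same in 39 and 38 of the 42 lists.

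The genes called after obstruction overlapped among the 3 treatments, whose comparisons share no library. Of the higher genes, 6217 were shared by the vehicle and early comparisons, 6331 by vehicle and late, and 6811 by early and late, against 3610, 3899 and 4237 for independent lists. Of the lower genes, 1877, 1826 and 1927 were shared, against 377, 361 and 374.

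The comparison of UUO early with UUO vehicle kidneys addressed the effect of the early course in obstructed kidneys. None of the named markers of injury and fibrosis passed. Havcr1 was at 188 ± 61.1 FPKM against 303 ± 76.2 FPKM (log2 -0.72, SE 0.28, adjusted p = 0.493), Lcn2 at 309 ± 247 against 166 ± 69.8 FPKM (adjusted p = 0.664). Col1a1 was at 174 against 133 FPKM (log2 0.27, SE 0.34, adjusted p = 0.843), Acta2 at 101 against 124 FPKM (adjusted p = 0.84) and Tgfb1 at 16.9 against 15.3 FPKM (adjusted p = 0.869). Col3a1, Fn1, Slc34a1, Lrp2, Umod, Aqp2, Adora1, Adora2b and Nt5e did not pass either, with adjusted p between 0.665 for Adora2b and 0.964 for Fn1. The drug target Adora2a was at 3.49 against 3.61 FPKM (log2 -0.04, SE 0.14, adjusted p = 0.958). The 2 genes that passed were Pfkfb3, a regulator of glycolysis (0.574 ± 0.367 to 4.31 ± 0.895 FPKM, log2 1.77, SE 0.28, adjusted p = 0.0165), and Dsel, a dermatan sulfate epimerase-like gene (0.0581 to 3.59 ± 0.705 FPKM, log2 2.11, SE 0.32, adjusted p = 0.0165). Both genes hold a transcript listed near 0 in at least 1 group and expressed in another. Of the genes with the smallest p that did not pass, Isoc1 was at 16.3 against 11.1 FPKM (adjusted p = 0.275). Dbp, a clock output transcription factor, was at 45.8 against 25.4 FPKM (log2 0.83, adjusted p = 0.276), and Ptrh2, Usp48 and Tspan12 followed.

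Of 19 circadian clock genes 17 had a positive difference (median log2 0.459). None passed over all genes, while 10 rose and 1 fell when adjusted over the list alone. Examples were the clock repressor genes Per3 (2.86 to 5.03 FPKM), Per2 (2.54 to 5.02 FPKM) and Nr1d2 (18.0 to 25.2 FPKM). The list was called at adjusted p = 3.04e-06, and at adjusted p = 0.0606 with an estimated correlation. Macrophage genes (23 of 24 positive, median log2 0.325, adjusted p = 3.94e-05), neutrophil genes (6 of 6, 1.29, adjusted p = 0.00291) and glycolysis genes (18 of 23, 0.161, adjusted p = 0.00291) were called higher. Proximal tubule genes were called lower (29 of 30 negative, -0.32, adjusted p = 0.00291). These lists, when the correlation was estimated, had adjusted p = 0.822, adjusted p = 0.822, adjusted p = 0.773 and adjusted p = 0.822. Among their members Pfkfb3 alone passed over all genes, and 2 glycolysis and 2 neutrophil genes rose when adjusted over the list alone. The neutrophil score of replicate 4 of this group was 7.02 against 2.64 to 2.82 in the other 3 libraries, its proximal tubule score was the lowest of the group at 3.95, and its S100a9 level was 873 FPKM against 27.3, 32.2 and 27.5 FPKM. Without this library the 4 lists lost their calls. The score difference went from -0.37 to 0.14 for proximal tubule (adjusted p = 0.338), 0.35 to 0.12 for macrophage (0.357), 1.32 to 0.24 for neutrophil (0.317) and 0.22 to 0.14 for glycolysis genes (0.141). Of the 10 lists called, the clock list alone kept its call without any single library. The muscle score was 4.12, 4.38, 2.42 and 5.96 in replicates 1 to 4 of this group, against 2.35 to 3.36 in UUO vehicle kidneys, so 3 of the 4 libraries lay above every UUO vehicle library. Muscle tissue expresses glycolysis genes, and whether the glycolysis list followed the muscle score was not tested. The matrix list was not called (22 of 31 positive, median 0.191, adjusted p = 0.195), nor were the adenosine list (adjusted p = 0.668) and the cAMP-responsive list (adjusted p = 0.511).

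By limma 2 genes passed, both higher, with 1161 at unadjusted p, and camera called 10 lists, 7 higher and 3 lower, of which 0 with an estimated correlation. The count of genes was 0 by limma without replicate 1 of UUO vehicle (1035 at unadjusted p) or replicate 1, 2 or 4 of UUO early (1104, 1375 and 920). It was 1 without replicate 4 of UUO vehicle, 8 without replicate 2 of UUO vehicle or 3 of UUO early, and 6 without replicate 3 of UUO vehicle. In simulated groups with no list changed and the libraries' residuals shuffled whole, the preset correlation called 12.1 of 42 lists on average (3 to 21 over 30 draws). The simulated false gene calls came with 200 genes changed, so they are not read against the 2 genes here.

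**Figure D3:**
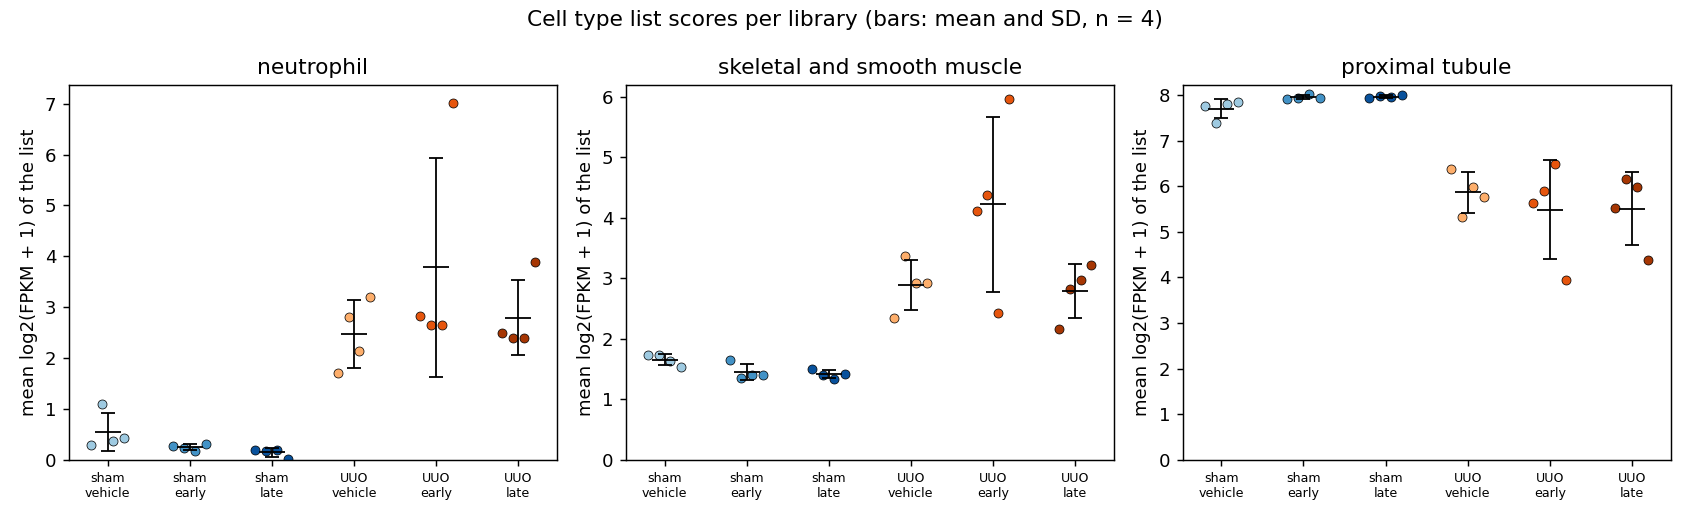
Mean log2(FPKM + 1) of the neutrophil, muscle and proximal tubule lists in each library of the 6 groups (points), with group mean and SD (bars, n = 4). Replicate 4 of UUO early had a neutrophil score of 7.02 and a proximal tubule score of 3.95. Replicates 1, 2 and 4 of UUO early had muscle scores of 4.12, 4.38 and 5.96.

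The comparison of UUO late with UUO vehicle kidneys addressed the late course in obstructed kidneys. Havcr1 was at 178 ± 63.1 against 303 ± 76.2 FPKM (log2 -0.81, SE 0.28, adjusted p = 0.336), Lcn2 at 163 against 166 FPKM (adjusted p = 0.999). Col1a1 was at 128 against 133 FPKM (log2 -0.13, SE 0.34, adjusted p = 0.939), Acta2 at 100.3 against 124 FPKM (adjusted p = 0.791) and Adora2a at 3.58 against 3.61 FPKM (adjusted p = 0.981). Col3a1, Fn1, Tgfb1, Slc34a1, Lrp2, Umod, Aqp2, Adora1, Adora2b and Nt5e did not pass, with adjusted p from 0.748 for Umod to 0.956 for Tgfb1. Among the genes that passed, the organic anion transporter Slco2b1 rose from 2.35 ± 3.75 to 13.4 ± 5.28 FPKM (log2 2.59, SE 0.50, adjusted p = 0.0376). Dbp rose from 25.4 to 52.3 FPKM (log2 1.04, adjusted p = 0.032) and the mitochondrial creatine kinase Ckmt1 from 18.4 to 33.4 FPKM (log2 0.83, adjusted p = 0.0102). The receptor kinase Mertk, which takes part in clearance of dying cells, rose from 6.98 to 12.5 FPKM (log2 0.74, adjusted p = 0.0129) and Cdh1, which encodes E-cadherin, from 58.5 to 84.1 FPKM (log2 0.52, adjusted p = 0.0197). Clec9a, a receptor of cross-presenting dendritic cells, rose from 1.19 to 4.26 FPKM (log2 1.27, adjusted p = 0.0376). The zinc finger gene Zfp317 fell from 6.94 to 1.73 FPKM (log2 -1.53, adjusted p = 0.0284).

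Kctd12, a subunit of GABA-B receptors, was listed at 0, 0, 0 and 3.95 FPKM in the UUO late libraries and at 11.6, 14.1, 13.7 and 2.74 FPKM in the UUO vehicle libraries (adjusted p = 0.0129). Micu3, a regulator of the mitochondrial calcium uniporter, rose from 0.571 ± 0.0661 to 2.70 ± 0.372 FPKM (log2 1.23, SE 0.09, adjusted p = 4.42e-08). With it went 1 transcript of the gene, which was listed at 0 in 16 libraries, at 5.47 ± 1.17 FPKM in UUO late and at 5.77 ± 1.04 FPKM in sham early kidneys. The remaining genes that passed were Galnt15, Epb41l4b, Htra4, Hepacam2, B3gnt7, Gm8126, Gm5799, AC166344.3 and Dsel, all higher. Circadian clock genes were called higher (15 of 19 positive, median log2 0.422, adjusted p = 2.09e-05), with 1 rising over all genes and 11 rising and 1 falling when adjusted over the list alone. All 10 intercalated cell genes had a positive difference (median 0.552, adjusted p = 1.04e-05), none passing over all genes and 4 rising when adjusted over the list alone, among them Foxi1, the master transcription factor of these cells (13.0 to 19.7 FPKM). Dendritic cell genes were called higher (7 of 8 positive, adjusted p = 0.00954), with Clec9a rising over all genes and 3 genes when adjusted over the list alone. Oxidative phosphorylation (22 of 24 negative, median -0.133, adjusted p = 1.13e-06) and proximal tubule genes (29 of 30 negative, -0.318, adjusted p = 2.24e-05) were called lower. These 5 lists, when the correlation was estimated, had adjusted p = 0.147, adjusted p = 0.748, adjusted p = 0.748, adjusted p = 0.873 and adjusted p = 0.925. Replicate 4 of UUO late had a proximal tubule score of 4.38 against 5.53 to 6.16 in the other 3 libraries. Without it the calls of the proximal tubule (score difference -0.35 to 0.02, adjusted p = 0.527) and dendritic cell lists (0.34 to 0.21, adjusted p = 0.155) ended. Of the 9 lists called, 3 kept their call without any single library: the clock, intercalated cell and oxidative phosphorylation lists. The matrix list was not called (12 of 31 positive, adjusted p = 0.0665).

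By limma 18 genes passed, 16 higher and 2 lower, and camera called 9 lists, 5 higher and 4 lower, of which 0 with an estimated correlation (2 at unadjusted p). The count of genes was 2 without replicate 3 of UUO vehicle, which ended every call of the 18 but that of Micu3 (adjusted p from 0.0507 for Ckmt1 to 0.121 for Slco2b1 among those named here). It was 31 without replicate 4 of UUO vehicle and 10 without replicate 2 of UUO late. It was 8 after median-of-ratios scaling and 3 when only the 2 compared groups were fitted, which ended the calls of Cdh1, Ckmt1 and Mertk (adjusted p = 0.275, 0.487 and 0.55). With the replicate number as a block 11 of the 18 stayed called. The calls of Slco2b1 (adjusted p = 0.0659), Dbp (0.0576), Clec9a (0.0659), Galnt15 (0.0659), Htra4 (0.0503), Gm8126 (0.0594) and Dsel (0.0589) ended. In simulated groups with no list changed the preset correlation called 12.9 lists on average. The simulated false gene calls came with 200 genes changed, so they are not read against the 18 genes here.

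**Figure D4:**
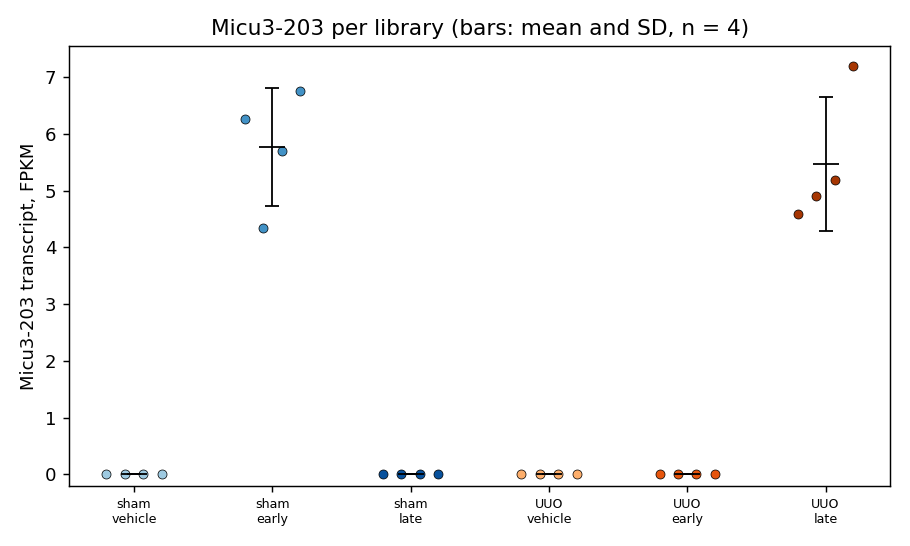
FPKM of 1 transcript of Micu3 in each library of the 6 groups (points), with group mean and SD (bars, n = 4). It was listed at 0 in 16 libraries and averaged 5.77 FPKM in sham early and 5.47 FPKM in UUO late kidneys.

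The comparison of UUO early with UUO late kidneys set the courses side by side in obstructed kidneys. Kctd12 was at 19.4 ± 5.57 FPKM in UUO early, against the 3 values of 0 and 1 of 3.95 FPKM in UUO late kidneys (log2 3.74, SE 0.44, adjusted p = 0.000216). Pfkfb3 was higher in UUO early (4.31 against 0.615 FPKM, log2 1.73, adjusted p = 0.0112). Micu3 (0.702 against 2.70 FPKM, log2 -1.12, adjusted p = 2.79e-07) and the predicted gene Gm8126 (1.18 against 7.63 FPKM, log2 -1.93, adjusted p = 0.00574) were lower. The genes with the smallest p that did not pass included the lipoprotein receptor Vldlr (3.77 against 7.36 FPKM), Hist1h2ap, a histone gene of a family of near-identical copies and so uncertain, Zc3h13, Ccdc88a and Bod1l. Glycolysis and hypoxia genes were called higher in UUO early (19 of 23 positive, median log2 0.177, adjusted p = 8.25e-06) and dendritic cell genes lower (7 of 8 negative, -0.388, adjusted p = 1.38e-05), with Clec9a at 1.41 against 4.26 FPKM (adjusted p = 0.0724). Matrix genes were called higher in UUO early (26 of 31 positive, 0.232, adjusted p = 0.000451), but not without replicate 1 of UUO early (score difference 0.24 to 0, adjusted p = 0.474). These lists, when the correlation was estimated, had adjusted p = 0.151, adjusted p = 0.151 and adjusted p = 0.888. Among their members Pfkfb3 alone passed over all genes, and 4 dendritic cell genes fell when adjusted over the list alone. The library with the neutrophil score of 7.02 belongs to this comparison too, and the muscle list was itself called higher (adjusted p = 0.0136). Muscle scores were 4.12, 4.38, 2.42 and 5.96 in UUO early against 2.16 to 3.21 in UUO late libraries. By limma 4 genes passed, 2 in each direction (1113 at unadjusted p), and camera called 11 lists, 9 higher and 2 lower, of which 0 with an estimated correlation. The count of genes was 8, 13 and 7 without replicate 2, 3 or 4 of UUO early and 7 without replicate 1 or 3 of UUO late. Simulated groups with no list changed gave 12.8 lists on average. The simulated false gene calls came with 200 genes changed, so they are not read against the 4 genes here.

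The comparison of sham early with sham vehicle kidneys addressed the early course in unobstructed kidneys. Micu3 alone passed (0.804 ± 0.12 to 2.86 ± 0.374 FPKM, log2 1.09, SE 0.09, adjusted p = 4.09e-07). The difference lay in 1 transcript, listed at 0 in every sham vehicle library and at 5.77 ± 1.04 FPKM in sham early. Another transcript of the gene was at 1.41 ± 0.23 FPKM in sham early and 2.09 ± 0.39 FPKM in sham vehicle. Transcript assignment therefore stays open for Micu3. Without switching genes limma gave 0 genes here (991 at unadjusted p). The RNA helicase Ddx17 (29.0 against 42.9 FPKM, log2 -0.55, adjusted p = 0.112), the dynactin subunit Dctn5 (10.4 against 27.2 FPKM, log2 -1.31, adjusted p = 0.112), Als2cl, Kti12 and Josd2 had the next smallest p. Circadian clock genes were called higher (15 of 19 positive, median log2 0.142, adjusted p = 0.000261), with the clock repressor Ciart at 8.36 against 3.63 FPKM (adjusted p = 0.148 for the gene). Proximal tubule genes were called higher (26 of 30 positive, 0.209, adjusted p = 0.000269) and endothelial genes lower (14 of 14 negative, -0.31, adjusted p = 0.000269), with no member of either passing, over all genes or adjusted over the list alone. The proximal tubule score was 7.39 in replicate 2 of sham vehicle against 7.75 to 7.85 in the other 3 libraries and 7.92 to 8.02 in sham early. The 3 lists, when the correlation was estimated, had adjusted p = 0.231, adjusted p = 0.874 and adjusted p = 0.874. By limma 1 gene passed, higher (1122 at unadjusted p), and camera called 9 lists, 3 higher and 6 lower, of which 0 with an estimated correlation. The count of genes was 2 without replicate 2 of sham vehicle or 3 of sham early, 3 without replicate 4 of sham early, and 103 with robust estimation and quality weights, and the count of lists was 14 without replicate 2 of sham vehicle.

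The comparison of sham late with sham vehicle kidneys addressed the late course in unobstructed kidneys. Podxl, a sialomucin of podocytes, fell from 25.4 to 13.4 FPKM (adjusted p = 0.0384). All 11 podocyte genes had a negative difference, 2 falling over all genes and 5 when adjusted over the list alone. The vascular growth factor receptors Flt1 (3.94 to 2.11 FPKM, adjusted p = 0.0203) and Kdr (4.58 to 2.62 FPKM, adjusted p = 0.0495) fell. All 14 endothelial genes had a negative difference (median log2 -0.497), 2 falling over all genes and 8 when adjusted over the list alone. The endothelial list had adjusted p = 0.000129 and the podocyte list adjusted p = 0.00753, and with an estimated correlation they had adjusted p = 0.965 and adjusted p = 0.805. The largest decreases included Pnn, which encodes the nuclear speckle protein pinin (11.5 to 5.48 FPKM, log2 -0.95, SE 0.12, adjusted p = 0.000791). Others were the chaperone cofactor Sdf2l1 (18.5 ± 12.4 to 6.08 ± 1.97 FPKM), Palm3, Hoxd4, Wsb1, Fhl2 and Rpl36a-ps1, a copy of a ribosomal protein gene and so uncertain. The increases were led by Itih2, a hyaluronan-binding protein gene (4.37 to 8.60 FPKM, log2 0.87, adjusted p = 0.0199), and included Tmem237, Lypla1, Alg3, Ccng1 and Ywhaz.

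Proximal tubule genes were called higher in sham late kidneys (27 of 30 positive, median log2 0.234, adjusted p = 0.000103) and so were circadian clock genes (13 of 19 positive, 0.091, adjusted p = 0.00628), with adjusted p = 0.965 and adjusted p = 0.805 with an estimated correlation. No member of either passed over all genes, and 1 clock gene rose when adjusted over the list alone. The proximal tubule scores were 7.93 to 8.00 in sham late, against the same sham vehicle libraries, of which replicate 2 was the lowest at 7.39. Without it the score difference went from 0.27 to 0.16 and the call stayed. The clock list lost its call without replicate 4 of sham vehicle (adjusted p = 0.0952). By limma 187 genes passed, 8 higher and 179 lower, and camera called 6 lists, 2 higher and 4 lower, of which 0 with an estimated correlation. Median-of-ratios scaling moved the median of all genes from -0.09 to 0.01 and gave 92 genes, 39 higher and 53 lower, of which 61 were among the 187. Rescaling to the same sum gave 330 genes, 7 higher and 323 lower. The count was 111, 30 and 107 without replicate 1, 2 or 3 of sham vehicle and 91, 34, 107 and 42 without replicate 1, 2, 3 or 4 of sham late. Of the 13 genes named for the size of their change, Pnn alone kept its call under every alternative.

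The difference between the drug effects in obstructed and in sham kidneys was tested as an interaction. For the early course Micu3 alone passed (log2 -0.98, SE 0.12, adjusted p = 0.00112), listed higher in sham early than in sham vehicle and not in obstructed kidneys. In both courses its interaction went with 1 transcript, listed at 0 in all groups but sham early and UUO late. Transcript assignment therefore stays open for it. Without switching genes limma gave 0 genes for the early interaction (606 at unadjusted p). For the late course Micu3 (log2 1.27, SE 0.12, adjusted p = 1.43e-05), Pnn (1.00, SE 0.17, adjusted p = 0.018), Fnbp4, which encodes a formin-binding protein (0.98, SE 0.16, adjusted p = 0.0172), and the endosomal adaptor gene Appl2 (0.80, SE 0.12, adjusted p = 0.0138) passed. Pnn was at 11.5 and 5.48 FPKM in sham vehicle and sham late, and at 14.7 and 15.2 FPKM in UUO vehicle and UUO late kidneys. All 30 proximal tubule genes had a negative interaction in both courses (median log2 -0.642 and -0.534, adjusted p = 2.53e-08 and 1.01e-09), and all 24 macrophage genes a positive one in the early course (0.539, adjusted p = 1.14e-07). With an estimated correlation these had adjusted p = 0.756, adjusted p = 0.913 and adjusted p = 0.756, and no member passed over all genes or adjusted over the list alone. These 3 stayed called without any single library, but their size rested in part on 1 library. Without replicate 4 of UUO early the early score interaction went from -0.63 to -0.11 for proximal tubule and from 0.60 to 0.38 for macrophage genes. Without replicate 4 of UUO late the late one for proximal tubule genes went from -0.62 to -0.24. By limma 1 gene passed for the early course (713 at unadjusted p) and 4 for the late course (1985), all 4 positive, and camera called 15 and 7 lists, of which 0 with an estimated correlation. The late count was 24 and 90 without replicate 2 or 4 of UUO vehicle, 8 and 1 without replicate 3 or 4 of sham late, and 31 and 7 without replicate 2 or 3 of UUO late. With the replicate number as a block the late count was 3, without Pnn (adjusted p = 0.0578). The early count was 4 without replicate 3 of UUO early. The counts of lists were 9 for the early course without replicate 1 of sham vehicle and 11 for the late course without replicate 1 of UUO late.

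Whether the drug moved genes against their obstruction change was tested across genes, with libraries that the 2 changes do not share. Over the 9920 genes called in UUO late against sham late kidneys, 42.7% had a change between UUO early and UUO vehicle of the opposite sign (r = 0.23 across genes, which are not independent replicates). Over the 9441 genes called in UUO early against sham early kidneys, 31.7% had a change between UUO late and UUO vehicle of the opposite sign (r = 0.285). Over all 13127 tested genes the 2 shares were 43.8 and 35.7%, so they are not particular to the called genes. The correlation was -0.141 for the early course without replicate 4 of UUO early and -0.096 for the late course without replicate 4 of UUO late, and 0.046 and 0.079 for the 2 courses without replicate 1 of UUO vehicle. It was 0.416 for the early course without replicate 3 of UUO early.

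The changes of the early and late courses in obstructed kidneys, both taken against the UUO vehicle libraries, correlated at r = 0.486 across genes. Unchanged groups that share simulated controls gave 0.443 ± 0.288 (SD, 100 draws), and the covariance was 0.0332 against 0.0335 ± 0.0245. Their residuals, those of the controls included, were drawn from the libraries of every UUO group, not from UUO vehicle alone. With the UUO vehicle libraries split between the courses in each of the 3 ways, the correlation averaged 0.046, 0.003 and 0.041.

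**Figure D5:**
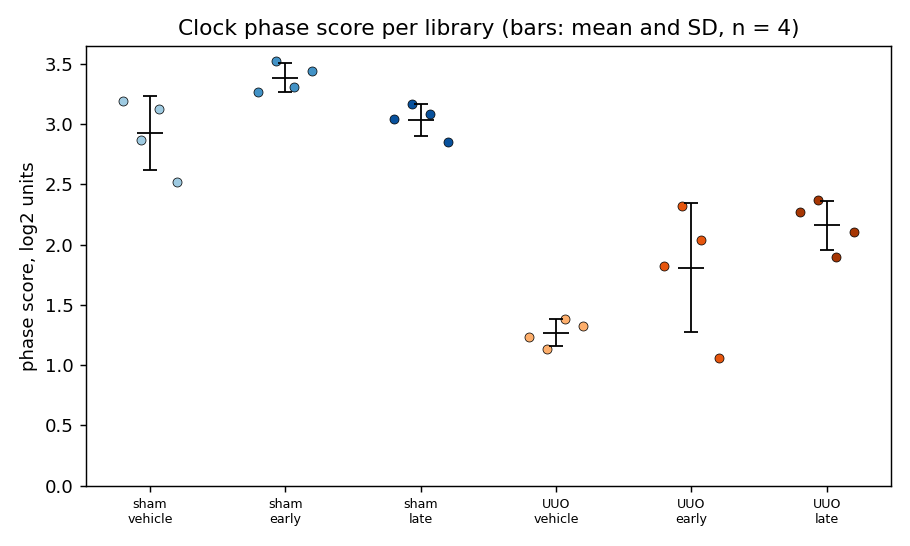
Clock phase score, the mean log2(FPKM + 1) of 10 clock genes less that of 5 clock genes of opposite phase, in each library of the 6 groups (points), with group mean and SD (bars, n = 4). The score averaged 2.93 in sham vehicle, 1.27 in UUO vehicle, 1.81 in UUO early and 2.16 in UUO late kidneys.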

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

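The test of switching transcripts and the test of a late-course effect in both surgeries were chosen only after the result was seen, as was the range of random gene sets below.

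Of 348 tests of a named gene's level in a group of 4 libraries, 33 had 1 library whose gap to the nearest other, divided by the group's range, was above Dixon's critical value, as had 13 of 252 tests of a list's mean level. Chance gives about 1 in 20. A ratio of 1 arises whenever all other libraries are listed at 0, whatever the size of the remaining value. This holds below for Mmp7 (0.18 and 0.115 FPKM) and Sprr2f (0.176 and 0.352 FPKM) in sham early and sham late. It holds too for Retnla in sham late and Kctd12 in UUO late (3.95 FPKM). Those flags by themselves set no library apart, and they are part of the 33, so that count is not read against 1 in 20. Replicate 4 of UUO early stood apart for Havcr1 (0.847), Lyz2 (0.96), the neutrophil list (0.959) and the glycolysis list (0.832). Replicate 4 of UUO late did so for Cyp2d9 (0.836), Lrp2 (0.847), Kctd12 (1), Slc7a13 (0.87) and the neutrophil list (0.938), as did replicate 2 of sham vehicle for Fn1 (0.882), Slc34a1 (0.902), Slc22a7 (0.849) and the fatty acid oxidation list (0.849). Replicate 1 of sham early stood apart for Mmp7 (1), Slc34a1 (0.9), Lypla1 (0.938), Slc7a13 (0.887), and the loop of Henle (0.848), glycolysis (0.84) and sex-linked lists (0.849). Replicate 4 of sham late stood apart for Mmp7 (1), Slco2b1 (0.966) and the neutrophil (0.922) and TGF-beta lists (0.874), and replicate 2 of sham late for Acta2 (0.872), Ywhaz (0.841) and the T cell (0.92) and complement lists (0.854). Replicate 3 of sham late stood apart for Sprr2f (1) and Retnla (1), replicate 3 of sham early for Sprr2f (1) and Col1a1 (0.86). The same held in replicate 1 of sham vehicle for Tgfb1 (0.899), Retnla (0.926) and the matrix list (0.927), and in replicate 3 of sham vehicle for Col1a1 (0.851). Among the rest were Fn1 in replicate 4 (0.893) and Fhl2 in replicate 2 of sham early (0.851), Sprr2f (0.937) and Tmem237 (0.87) in replicate 1, Ubd in replicate 2 (0.861) and Itih2 in replicate 3 of UUO late (0.958). The last were Mertk (0.918) and Itih2 (0.959) in replicate 2 and the prostaglandin list in replicate 1 of UUO early (0.89), and Kctd12 in replicate 4 of UUO vehicle (0.87).

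Some genes and lists passed a test of the difference between courses or surgeries itself. Between UUO early and UUO late these were Kctd12 (log2 3.74), Pfkfb3 (1.73), Micu3 (-1.12), Gm8126 (-1.93) and 11 lists. Of these genes Kctd12, Pfkfb3 and Micu3 hold a switching transcript, and transcript assignment stays open for them. Between surgeries they were Micu3 (-0.98) and 15 lists for the early course, and Micu3 (1.27), Pnn (1.00), Fnbp4 (0.98), Appl2 (0.80) and 7 lists for the late course. With an estimated correlation camera called 0 lists in each of the 3. Other splits of the same libraries gave up to 22, 21 and 21 lists, and simulated groups with no list changed gave 12.8 on average for UUO early against late, so these counts of lists show no difference. In the transcript table, outside the gene comparisons, 1 Micu3 transcript averaged 5.77 FPKM in sham early and 5.47 FPKM in UUO late, and was listed at 0 in the other 16 libraries.

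The genes called in UUO late against UUO vehicle kidneys were weighed against the way the submitters' quantification assigns reads to transcripts. Of the 18 genes 22.2%, namely Micu3, Zfp317, Kctd12 and Dsel, hold a transcript that switches between near 0 and expressed in these 2 groups, against 3.23% of the 13127 tested genes. A switch between these same groups makes a gene more prone to pass by itself, so the higher share supports nothing. Transcript assignment stays open for the 4 genes. The other 14 hold no transcript that switches between these 2 groups, though Cdh1 holds 1 that switches between other groups of the same surgery. An effect of the late course shared by both surgeries is argued against as the source of the whole set. The sham late changes of the 18 genes, taken in their UUO late direction, had a median of log2 -0.04 (SD 0.16), against a median size of 0.96 and a smallest of 0.48 in UUO late kidneys. For single genes it stays open, as for Dbp (log2 0.41 in sham late, unadjusted p = 0.0428). A response particular to obstructed kidneys was not tested apart from the interaction, which passed for Micu3 alone of the 18.

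The 187 genes called in sham late against sham vehicle kidneys, 179 of them lower, were weighed against scaling, depth and a single library. After median-of-ratios scaling 32.6% of them (61) were still called and 57.6% of all calls were lower, while rescaling to the same sum gave 330 genes, 323 of them lower and 185 of them among the 187. The 2 scalings disagree, so whether scaling accounts for the excess of lower genes stays open. Lower depth of the sham late libraries stays open: the called genes had a median of 5.92 FPKM in sham vehicle against 4.86 for all tested genes, opposite to a loss at the floor, yet within the range of 10000 random sets of the same size (3.67 to 6.4). A single library stays open too, since the count fell to 30 without replicate 2 of sham vehicle, but it fell under 0.5 of its size for 4 of the 8 libraries, so the fall is not particular to any of them, a reading made after the counts were seen. The sham early libraries, against the same sham vehicle libraries, had the same sign for 182 of the 187 genes (median log2 -0.25 against -0.50), and an effect of the drug remains untested against a feature of the shared sham vehicle libraries.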

How the results depend on the processing

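Leaving out switching genes, and replicate 4 of UUO early and UUO late together, were chosen only after the result was seen. The total counts of genes in the 3 comparisons of UUO with sham kidneys stayed within 1.5 times under every alternative run. Without single libraries they ranged from 8244 to 8712 under vehicle, 9027 to 9394 under the early and 9480 to 9743 under the late course. The split by direction and the genes called were less stable. Median-of-ratios scaling took the vehicle comparison from 6604 to 4199 higher and from 2186 to 3899 lower genes. It kept 6405 of the 8790 calls under vehicle, 6973 of 9441 under the early and 7248 of 9920 under the late course. Of the named genes' results over all alternatives in these 3 comparisons, 470, 288 and 287 kept direction and side of the threshold, and 3 became past it. Of their list members named, 1 reversed: Bpgm, in UUO late against sham late kidneys, was at log2 -0.45 after median-of-ratios scaling, and the cause was not tested. With a pseudocount of 0.1 the counts were 1 for UUO early and 6 for UUO late against UUO vehicle, 400 for sham late, 2 for UUO early against late and 31 for the late interaction. With no filter UUO early against late gave 8. With a filter at 5 FPKM, which tests fewer genes, limma gave 0 for UUO early (743 at unadjusted p), 6 for UUO late, 0 for sham early (824), 1 for UUO early against late and 0 for the early interaction (441). Median-of-ratios scaling gave 1 for UUO early, 8 for UUO late and 92 for sham late, with 14 lists for sham early and 11 for sham late. Rescaling to the same sum gave 1, 8 and 330 genes, and 102 for the late interaction. Fitting the compared groups alone gave 6, 3, 7 and 84 for UUO early, UUO late, sham early and sham late, and 2 for the early interaction. Robust estimation with quality weights gave 0 (905 at unadjusted p), 34, 103 and 814, with 36 for UUO early against late and 71 for the late interaction. The replicate block gave 1 for UUO early and 8 for UUO early against late. Without switching genes limma gave 0 for UUO early (1023), 0 for sham early (991), 1 for UUO early against late and 0 for the early interaction (606). Without replicate 4 of UUO early and of UUO late it gave 1 for UUO early, 33 for UUO late and 8 for the late interaction. Except where fewer genes or libraries entered by construction, the cause was not tested. With an estimated correlation camera called 0 lists in each of the 10 comparisons, against 8, 1, 2, 1, 2, 3, 5, 3, 2 and 1 at unadjusted p, in the order UUO vehicle against sham vehicle, UUO early and UUO late against UUO vehicle, sham early and sham late against sham vehicle, UUO early against late, UUO early against sham early, UUO late against sham late, and the early and late interactions. Without single libraries the gene counts of the drug comparisons, in the same order, were 0 to 8, 2 to 31, 1 to 3, 30 to 168 and 4 to 13, and those of the interactions 1 to 4 and 1 to 90. The list counts were 25 to 28, 8 to 15, 8 to 11, 6 to 14, 4 to 9, 9 to 15, 22 to 23, 23 to 25, 9 to 18 and 6 to 11. The reversal correlation ranged from -0.141 to 0.416 and changed sign in the early course without replicate 4 of UUO early (-0.141) and in the late course without replicate 4 of UUO late (-0.096). It also moved to 0.046 and 0.079 in the early and late course without replicate 1 of UUO vehicle. Over all tested genes it was 0.187 and 0.215. Splitting the UUO vehicle libraries between the courses took the agreement from 0.486 to 0.046, 0.003 and 0.041, since shared controls then no longer enter both sides. Of the named genes' results, 136 of UUO late and 74 of sham late were no longer past the threshold. The same held for 17 of UUO early, 7 of UUO early against late and 7 of the late interaction. Of the list members' results in sham late against sham vehicle, 56 were no longer past the threshold and 53 became past it. The depth, estimated at 7720000 to 19680000 fragments per library, limits what can be said of genes below the filter of 1 FPKM, which were not tested.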

Other observations

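The clock tests below were chosen only after the result was seen. Lists not described above had these results for UUO vehicle against sham vehicle kidneys, none called by camera. Of 12 urothelial genes 11 rose, or 12 when adjusted over the list alone (median log2 2.50, adjusted p = 0.128), such as the basal keratins Krt5 (1.17 to 46.8 FPKM) and Krt14 (0.481 to 35.4 FPKM). Prostaglandin genes (9 of 13 rose, 2 fell, adjusted p = 0.345), B cell genes (4 of 5 rose, 0.278), NK cell genes (3 of 3 rose, 0.0771), and lymphatic endothelial genes (3 of 5 rose, 1 fell, or 4 and 1 when adjusted over the list alone, 0.587) went mostly up. Of 6 muscle genes 3 rose (0.661). Renin-angiotensin and blood pressure genes went both ways (6 of 17 rose, 5 fell, 0.204), with endothelin Edn1 from 0.611 to 10.5 FPKM and Klotho, Kl, from 47.2 to 12.5 FPKM. Xenobiotic response genes also went both ways (5 of 14 rose, 5 fell, 0.201), and blood (1 of 7 fell, 0.0897), adipocyte (1 of 11 fell, 0.204) and sex-linked genes (1 of 4 rose, 0.805) changed little. Mast cell and adrenal lists had too few tested genes, 0 of 7 and 1 of 11.

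Further lists called by camera lost the call with an estimated correlation. Against UUO vehicle, UUO early kidneys had adipocyte (adjusted p = 0.00711), prostaglandin (0.011) and principal cell genes (0.0256) higher and cell cycle (0.011) and oxidative phosphorylation genes (0.0358) lower, at adjusted p = 0.822, 0.773, 0.773, 0.822 and 0.822 with an estimated correlation. Each also lost its call without at least 1 single library. UUO late kidneys had antigen presentation (0.0391) and loop of Henle genes (0.0441) higher and cell cycle (0.00044) and antioxidant genes (0.0195) lower, each at 0.925, and each lost its call without at least 1 library. Against UUO late, UUO early kidneys had complement (0.000346), adipocyte (0.00198), macrophage (0.00496), neutrophil (0.00496), cytokine (0.0071), oxidative phosphorylation (0.00792) and muscle genes (0.0136) higher and intercalated cell genes (0.00496) lower, at 0.558 for complement, 0.638 for muscle and 0.888 for the others. Without replicate 4 of UUO early the score difference turned for macrophage (0.22 to -0.01, adjusted p = 0.786), neutrophil (0.99 to -0.09, 0.875) and cytokine genes (0.19 to -0.11, 0.504). The complement (0.125) and intercalated cell calls (0.16) ended too. Oxidative phosphorylation genes lost theirs without replicate 4 of UUO late, where their score difference turned (0.07 to -0.03, 0.981). Muscle genes lost theirs without 2 of the 8 libraries in turn. Sham early kidneys had interferon (0.00703), myofibroblast (0.0179), matrix (0.0189), podocyte (0.031) and macrophage genes (0.031) lower and fatty acid oxidation genes higher (0.0468, median log2 0.045, mean -0.015), each at 0.874, and each lost its call without at least 1 library. Sham late kidneys had cell cycle (0.0286) and immediate early genes (0.0414) lower, each at 0.965. Without replicate 3 of sham vehicle the cell cycle score difference went from -0.30 to -0.12 (0.901), and without replicate 2 of sham vehicle that of immediate early genes from -0.53 to -0.27 (0.487).

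In the same way, the early interaction had interferon (0.000104), matrix (0.00295), prostaglandin (0.00295), podocyte (0.00725), complement (0.0132), neutrophil (0.0167), antigen presentation (0.0201), matrix protease (0.0227), NF-kB (0.0301) and endothelial genes (0.0475) positive and oxidative phosphorylation (0.00107), fatty acid oxidation (0.0201) and blood genes (0.0358) negative, each at adjusted p = 0.756 with an estimated correlation. The late interaction had podocyte (0.001), intercalated cell (0.00244) and endothelial genes (0.0176) positive and oxidative phosphorylation (3.35e-07), antioxidant (0.001) and fatty acid oxidation genes (0.0176) negative, at 0.768 for podocyte and 0.913 for the others. Of these the podocyte, interferon and prostaglandin lists of the early interaction kept their calls without any single library. So did the podocyte, intercalated cell, oxidative phosphorylation and antioxidant lists of the late interaction. Positive and negative are test directions relative to all tested genes, whose median interaction was 0.06 early and 0.14 late. The fatty acid oxidation score had a late interaction of 0, and of 0.17 without replicate 4 of UUO late (adjusted p = 0.366). Without replicate 4 of UUO early its early interaction went from -0.11 to 0.14 (0.618). There the NF-kB score went from 0.25 to 0.06 and its test direction turned (0.892).

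Muscle scores were 4.12, 4.38, 2.42 and 5.96 in replicates 1 to 4 of UUO early against 2.35 to 3.36 in UUO vehicle libraries, so the higher score is not particular to replicate 4. Replicate 4 of UUO early had the parvalbumin gene Pvalb at 724 FPKM against 12.7, 35.6 and 0.148 FPKM. Its Krt5 level was 335 FPKM against 21.4, 79.4 and 53.5 FPKM. The skeletal muscle actin gene Acta1 was at 23, 52.3, 0.966 and 1000 FPKM in replicates 1 to 4 of UUO early. It was at most at 2.38 FPKM in UUO vehicle libraries. Its order over the UUO early libraries was that of Pvalb, so the Pvalb values cannot be read as tubule expression alone. No explanation was tested for the Pvalb and Krt5 values, and Pvalb, Acta1 and Krt5 were chosen here after their values were seen.

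The counts of splits below include the real split, so 1 means that no other split gave as many calls. As many genes were called in 1 of 35 splits of the same libraries for UUO vehicle against sham vehicle (8790 against at most 2855 in the others), 1 of 35 for UUO early against sham early (9441 against 4304) and 1 of 35 for UUO late against sham late (9920 against 3). The same held in 1 of 35 for sham late against sham vehicle (187 against 1). These splits argue against chance in the 4 comparisons but do not exclude it. A share of 1 in 35 is the smallest they can give, and it was not adjusted over the 10 comparisons. For sham late the count fell to 30 without replicate 2 of sham vehicle. There the splits cannot tell the drug from another feature of the sham vehicle libraries. For the late interaction 4 of 100 gave as many (4 against 99), a share under 0.05. However, 2 other splits gave over 3 times the real count, and leaving out single libraries gave 1 to 90 genes. The split with 99 genes keeps the real groups of sham late and sham vehicle and mixes the UUO libraries, so it holds the sham difference, and nothing is read from that share. Chance cannot be excluded for UUO early against UUO vehicle (13 of 35, 2 against 24), UUO late against UUO vehicle (2 of 35, 18 against 28), sham early (9 of 35, 1 against 4). Nor can it for UUO early against UUO late (8 of 35, 4 against 830) and the early interaction (20 of 100, 1 against 4). The split with 830 genes, several times the real count, points to a structure of the samples whose source was not tested. It sets replicates 1 and 4 of both UUO early and UUO late against the others. By the splits, chance cannot be excluded for any count of lists. In the 3 comparisons of UUO with sham kidneys many other splits are uneven and keep part of the obstruction difference, so their counts of lists decide nothing. There the tubular injury score was 3.13 (SD 0.14) in sham vehicle against 6.34 (SD 0.14) in UUO vehicle, and the macrophage score 2.02 (SD 0.07) against 5.05 (SD 0.32). As many lists were called in 6 of 35 splits for UUO vehicle against sham vehicle (26 against 28), 27 for UUO early (10 against 21) and 23 for UUO late against UUO vehicle (9 against 18). The counts were 7 for sham early (9 against 12), 13 for sham late (6 against 10), 31 for UUO early against late (11 against 22), 13 for UUO early against sham early (23 against 30) and 6 for UUO late against sham late (24 against 27). They were called in 22 of 100 for the early (15 against 21) and 68 of 100 for the late interaction (7 against 21).

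Camera called clock genes higher with either course in both surgeries at the preset correlation. With an estimated correlation they had adjusted p = 0.0606 in UUO early, 0.147 in UUO late, 0.231 in sham early and 0.805 in sham late kidneys, and Dbp in UUO late alone passed over all genes. A different clock phase was weighed as a hypothesis, whether from the hour of collection or from a shift by the drug. A score that takes 10 of these genes less 5 of opposite phase was 0.50 higher in drug than in vehicle libraries on average over both surgeries, 0.72 in UUO and 0.29 in sham kidneys. It holds the genes that made the pattern, and it was 2.93 in sham vehicle against 1.27 in UUO vehicle kidneys, so it supports no phase difference by itself. The 5 opposite-phase genes, which a phase difference would lower, differed by a mean log2 of -0.04 (exact two-sided permutation p = 0.612). A phase difference therefore stays open, and the labels give no hour of collection. A smaller obstruction change under the drug would leave the sham kidneys without a difference, and the 0.29 there does not decide it.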
